A study of Mus musculus with 60 samples.

How the data were processed

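Total RNA from 6 mouse tissues was read as bulk RNA-seq in 60 libraries, with RNeasy extraction and a stranded total RNA library kit per the labels' protocols. The deposited files hold raw read counts per Ensembl gene, as whole numbers and without normalization, per the file headers and the values, and the genome build is GRCm38 per the submitters' processing notes. The aligner, the counting tool with its strand setting and the gene annotation are not given in the sources used here. Mice carried a doxycycline-inducible cassette of 4 factors and rtTA, and the treated old mice drank doxycycline at 1 mg/ml for 2 days on and 5 days off in each week for 1 month from the age of 25 months, per the labels. No group received doxycycline without the cassette, so the drug and the factors are not separated.

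The 60 single files were checked against the series table and were identical to it. Of 52636 gene identifiers 52403 matched a symbol and a position, and those without a match held 0.023% of all counts. Libraries of the same group differed beyond sampling noise in every pair (lowest chi-square per degree of freedom 10.29), as separate samples do. Intervals and floors (3 counts of the total) cover counting error only. Groups were taken from the labels. Replicates are numbered by the order of the records, which pairs no samples between groups. Sample numbers in the labels run in blocks of 6, with 1 library of each tissue and the same group and sex, so a block may be 1 animal. The labels do not say so, and no test used the blocks.

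Each tissue was fitted on its own with all 10 libraries in edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, a quasi-likelihood fit with group and sex, and Benjamini-Hochberg adjusted p under 0.05 as the threshold of a call. All edgeR, camera and fry tests were two-sided. The comparisons were untreated old minus young (age), induced old minus untreated old (4F induction) and induced old minus young. CPM of named genes are TMM-scaled, and levels given as CPM of the library total, with those of Alb, Cela1, Hba-a1, Kap, Krt71, Mki67, Myh6, Plin1 and Prss2 and of Trem2 in lung, are without scaling. For 47 gene lists (622 genes, of which 2 had no match), fixed with the groups, tests and most alternatives before the data were examined, camera (limma 3.58.1) was run with a preset inter-gene correlation of 0.01 where at least 3 members passed the filter. Camera with an estimated correlation and fry were alternatives. Counts of list members are given over all genes and adjusted over the list alone.

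Genes were named by a fixed rule: per tissue, for age and for 4F induction, the 6 genes that rose and the 6 that fell most among those called with an average log2 CPM of at least 1 and no overlap between groups, the 4 cassette factors, up to 4 called members of each list with a passing test or at least 3 calls (other members as values only), and genes called alike with 4F induction in at least 2 tissues (up to 10) or with age in at least 5 (up to 15). That last part named no gene. Among the genes the rule names, those given were mainly ones that kept their call without any single library, a choice made after their values were seen, as was the choice of list members given as values and of marker genes for other tissues.

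The age axis used limma on log2 CPM with a prior count of 2 and 500 genes of smallest p, with each untreated old library held out in turn, and an exact two-sided permutation test of 3 against 3 libraries. Fold-change correlations were set beside 20 simulated data sets with an unchanged treated group, which draw genes independently and hold no variation shared by a whole library. The variance of list effects between tissues was tested with 100000 permutations of the group labels, drawn in each tissue separately, which treats tissues as independent. The null of that test is no group effect in any tissue, not equal effects. An effect shared by the tissues widens the permuted variance and makes a list less likely to pass. Alternatives were DESeq2 1.42.0 as test and its size factors as scaling, no low-count filter, no sex covariate, only the compared groups in the fit, glmTreat against a 1.5-fold change, leaving out mitochondrial, ribosomal RNA and haemoglobin genes, 200 axis genes, and leaving out each library in turn. Figures and tables were made in Python 3.11.15.

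The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. For age, 0% to 84% of the 2-fold and 23% to 97% of the 4-fold changes were recovered across tissues with 16851 to 19630 genes, and for 4F induction 0% to 82% and 2% to 96%. The lowest values were in skin. At most 11 unchanged genes were called. The first tolerance asked for at least 30% recovery at 4-fold in each of 12 tests and an axis difference from -0.8 to -0.2 for a planted -0.5. It was missed in 2 of the 12 tests and in 1 tissue of the axis test, all in skin, and was then replaced by a limit of 0.1 on the error of the median log2 fold change (highest 0.056) and a check of false calls. The axis difference recovered in skin was -0.14. In skin 0% of 2-fold changes were recovered in both comparisons, and 23% of 4-fold changes for age and 2% for 4F induction over 19188 genes, so most changes of either size were not detectable with these libraries.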

Results

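Bulk RNA-seq read counts per gene were available for 60 mouse libraries, 10 from each of kidney, liver, lung, skeletal muscle, skin and spleen. In each tissue 4 libraries came from young mice (3 months, 2 male and 2 female) and 3 from untreated old mice (26 months, 2 male and 1 female). The last 3 came from old mice of the same age and sexes in which 4 reprogramming factors (4F: Oct4, encoded by Pou5f1, with Sox2, Klf4 and c-Myc) had been induced in cycles for 1 month. The mice carried 1 doxycycline-driven cassette for the 4 factors together with the rtTA transactivator, and the untreated old mice were of the same genotype as the induced ones. Only the induced mice received doxycycline, for 2 days of each week from the age of 25 months. Libraries held 16.7 to 50.7 M counts (M, mega; median 28.4 M). The ranges were 22.9 to 50.7 M in kidney, 25.6 to 39.2 in liver, 24.1 to 31.7 in lung, 25.5 to 39.9 in muscle, 17.5 to 27.4 in skin and 16.7 to 32.2 in spleen. The labels give each library as a separate sample and do not state which libraries came from the same animal, so p-values measure the spread between samples. Levels are in CPM (read counts scaled to a common library total), differences are log2 fold changes with standard errors, and positions are 1-based on GRCm38.

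The first comparison asked which transcripts differ between untreated old and young mice. In aged kidney, macrophage, T and NK cell, complement and p53 target lists lay higher and clock output genes lower. These lists passed camera at the preset correlation and none with an estimated one. The labels give no time of collection. Clock changes with age, here and in other tissues, thus cannot be told apart from time of day. Pik3c2g, which encodes a class II phosphoinositide 3-kinase (chromosome 6, 139587221 to 139969284), fell from 39.4 ± 1.91 CPM (SD, n = 4) to 10.4 ± 0.62 CPM (SD, n = 3), a log2 change of -1.91 (SE 0.08, edgeR adjusted p = 1.85e-05). Arntl, the core clock activator (chromosome 7, 113207465 to 113314126), rose by 2.45 (SE 0.23, adjusted p = 0.00244). Eda2r, a p53-induced receptor of the tumour necrosis factor family (chromosome X, 97333840 to 97377216), rose by 2.40 (SE 0.31, adjusted p = 0.00832), a call lost without the sex covariate. Ugt1a9, a glucuronosyltransferase gene (chromosome 1, 88070800 to 88218997), fell by 6.10 (SE 0.35, adjusted p = 0.000101), although genes of this locus share 3' exons and the counting may split their reads.

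Among the gene lists, 9 of 12 measured macrophage markers rose in kidney and 3 did not pass, and all 12 rose when adjusted over the list alone (camera adjusted p = 1.51e-13, and adjusted p = 0.196 with an estimated correlation). Of 14 T and NK cell markers 8 rose and 6 did not pass, with 12 rising when adjusted over the list alone (camera adjusted p = 5.23e-11, adjusted p = 0.282 with an estimated correlation). Complement genes rose in 6 of 12 cases and 6 did not pass, with 7 rising when adjusted over the list alone (camera adjusted p = 5.31e-09, adjusted p = 0.221 with an estimated correlation). Of 14 p53 targets 8 rose, 1 fell and 5 did not pass, against 9 rising and 2 falling when adjusted over the list alone (camera adjusted p = 8.71e-07, adjusted p = 0.066 with an estimated correlation). Ccng1 rose by 0.59 (SE 0.08) and Zmat3 by 0.40 (SE 0.06), and both calls were lost without old untreated 3 and without the sex covariate. Clock genes that peak with PER and DBP fell in 8 of 12 cases, and in all 12 when adjusted over the list alone (camera adjusted p = 1.21e-19, adjusted p = 0.0793 with an estimated correlation). Cry2, a repressor of the clock, changed by -0.57 (SE 0.07), Bhlhe41 by -1.35 (SE 0.13, a call lost without the sex covariate) and Ciart by -1.85 (SE 0.24). In total 700 genes rose and 455 fell of 18878 tested. Of these 1155, 810 had no overlap between the groups, a share raised by their selection. Over all tested genes it was 14.4%, where chance gives 5.71%. Leaving out 1 library gave 1096 genes without old untreated 1, 352 and 127 without old untreated 2 and 3, and 250, 147, 749 and 442 without young 1, 2, 3 and 4. Without the sex covariate the count was 101, and DESeq2 called 2188.

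In liver, macrophage and neutrophil markers were higher in untreated old mice, while the oxidative phosphorylation and cholesterol synthesis lists lay lower with few or no members passing over all genes. Krt23, a type I keratin (chromosome 11, 99477974 to 99493137), fell from 5.24 ± 2.24 CPM (SD, n = 4) to 0.275 ± 0.119 CPM (SD, n = 3), a log2 change of -4.05 (SE 0.30, adjusted p = 0.00796). Igsf23, an immunoglobulin superfamily member (chromosome 7, 19937305 to 19950756), fell by 4.44 (SE 0.41, adjusted p = 0.00914). Neutrophil markers rose in 6 of 12 cases and did not pass in 6, and all 12 rose when adjusted over the list alone (camera adjusted p = 2.7e-08, adjusted p = 0.439 with an estimated correlation). Macrophage markers rose in 7 of 12 cases and in all 12 when adjusted over the list alone (camera adjusted p = 8.33e-08, adjusted p = 0.439 with an estimated correlation). Trem2, a lipid-sensing receptor of macrophages, rose by 6.29 (SE 1.47, adjusted p = 0.0458) and stood at 11.6, 77.9 and 1.15 CPM in the 3 untreated old livers. The proliferation marker Mki67 reached 190 CPM of the library total in old untreated 2, the library with the highest Trem2.

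Genes for nuclear-encoded subunits of oxidative phosphorylation were lower in aged liver for 22 of 22 members, none of which passed over all genes, while 18 fell when adjusted over the list alone (camera adjusted p = 1.52e-07, adjusted p = 0.45 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 19 cases, Mvk and Stard4 among them, and in 9 when adjusted over the list alone (camera adjusted p = 2.85e-07, adjusted p = 0.439 with an estimated correlation). Kidney transcripts stood apart in liver young 4, with Kap at 27.3 CPM of the library total and at most 0.0961 in the other livers. Of all tested liver genes 30.3% had no overlap between the groups (chance 5.71%). In liver 909 genes rose and 431 fell of 16941 tested, 1269 of them without overlap. That count rested on single libraries: it was 67, 726 and 3782 without old untreated 1, 2 and 3, and 4, 2, 35 and 79 without young 1, 2, 3 and 4. Krt23 kept its call in all 7 of these fits and Igsf23 lost it without young 2 (adjusted p = 0.0562, over a range of 1.67e-23 to 0.0562). Trem2, Mvk and Stard4 each lost theirs without old untreated 1 and without each of young 1 to 4, and Trem2 and Mvk also without old untreated 2. DESeq2 called 4467 genes in liver.

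In lung, interferon-stimulated, antigen presentation and complement genes were higher with age, and collagen, endothelial and clock output genes were lower. Col6a3, which encodes a chain of type VI collagen (chromosome 1, 90765923 to 90843971), fell from 160 ± 4.42 CPM (SD, n = 4) to 60.6 ± 5.02 CPM (SD, n = 3), a log2 change of -1.42 (SE 0.09, adjusted p = 0.00121). Cxcl9, a chemokine induced by interferon gamma (chromosome 5, 92321347 to 92328079), rose by 6.44 (SE 1.05, adjusted p = 0.00855), and Gzmk, a granzyme of T cells (chromosome 13, 113171608 to 113225908), rose by 6.85 (SE 1.23, adjusted p = 0.0113). Interferon-stimulated genes rose in 18 of 22 cases and in 21 when adjusted over the list alone (camera adjusted p = 1.57e-13, adjusted p = 0.313 with an estimated correlation). MHC class I genes rose in 9 of 10 cases, and in all 10 when adjusted over the list alone (camera adjusted p = 8.69e-08, adjusted p = 0.313 with an estimated correlation), with H2-K1 at 1.51 (SE 0.30). Complement genes rose in 9 of 12 cases, among them C4b at 1.66 (SE 0.15). C7 fell by 1.43 (SE 0.19), with the same counts when adjusted over the list alone (camera adjusted p = 1.57e-06, adjusted p = 0.262 with an estimated correlation). Fibrillar collagen and matrix genes fell in 11 of 19 cases, including Col1a1 at -1.24 (SE 0.12) and Col1a2 at -1.35 (SE 0.12), and 1 rose. The list gave 14 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.43e-11, adjusted p = 0.262 with an estimated correlation). Endothelial markers fell in 5 of 10 cases and in 9 when adjusted over the list alone (camera adjusted p = 5.73e-06, adjusted p = 0.313 with an estimated correlation), with the receptor genes Kdr at -1.37 (SE 0.23) and Tek at -1.12 (SE 0.15). Clock genes of the PER and DBP phase fell in 10 of 12 cases and in 11 when adjusted over the list alone (camera adjusted p = 2.43e-11, adjusted p = 0.262 with an estimated correlation).

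Transcripts of other tissues moved with the lung groups. Albumin stood at 263 and 608 CPM of the library total in old untreated 1 and 2, at 15.1 in old untreated 3 and at no more than 8.15 in the other 7 lung libraries. Hepatocyte genes rose in 9 of 15 cases and 1 fell, against 11 and 2 when adjusted over the list alone (camera adjusted p = 6.88e-06, adjusted p = 0.313 with an estimated correlation), and 98 of the 3478 age-dependent lung genes belonged to 174 liver-enriched genes. Myh6, the atrial myosin heavy chain, was at 838, 201, 212 and 261 CPM in the young lungs and at no more than 35.3 in the old ones. Plin1, the lipid droplet protein of fat cells, stood at 30.6, 129, 49.6 and 9.62 in the young lungs. In the untreated old lungs it stood at 7.26, 2.96 and 3.46. Of all tested lung genes 36.6% had no overlap between the groups (chance 5.71%). In all, 1643 lung genes rose and 1835 fell of 19630 tested, 3293 of them without overlap. The count was 3387 without the liver-enriched genes and 584 (368 up, 216 down) without old untreated 1 and 2 together, which leaves 1 untreated old library, assumed to vary like the other groups. These 2 alternatives were chosen after seeing the data. Leaving out single libraries gave 1771 and 2288 without old untreated 1 and 2, and 1433, 1496 and 1767 without young 1, 2 and 4.

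In skeletal muscle, mitochondrial transcripts were higher with age. All 13 mitochondrially encoded transcripts rose, as they did when adjusted over the list alone (camera adjusted p = 3.23e-19, adjusted p = 0.559 with an estimated correlation). The cytochrome oxidase transcript mt-Co2 rose from 33.8 ± 7.28 CPM (SD, n = 4) to 96 ± 18 CPM (SD, n = 3). These levels are low beside the fast fibre gene Ckm, at 16000 to 19100 CPM of the library total in young muscle. How the upstream counting treated mitochondrial reads is not given. Nuclear genes of oxidative phosphorylation rose in 10 of 22 cases and in 14 when adjusted over the list alone (camera adjusted p = 5.61e-07, adjusted p = 0.559 with an estimated correlation). Ndufb5 of complex I rose by 1.07 (SE 0.20) and Cox6c of complex IV by 1.04 (SE 0.19). Clock genes of the PER and DBP phase fell in 6 of 12 cases and in 9 when adjusted over the list alone (camera adjusted p = 1.12e-07, adjusted p = 0.559 with an estimated correlation). The clock output regulator Hlf (chromosome 11, 90336536 to 90390895) fell from 40 ± 5.47 CPM (SD, n = 4) to 12 ± 1.32 CPM (SD, n = 3), a log2 change of -1.79 (SE 0.18, adjusted p = 0.00313). Lipid synthesis genes fell in 6 of 12 cases and in 8 when adjusted over the list alone (camera adjusted p = 5.44e-05, adjusted p = 0.559 with an estimated correlation), among them Scd1, a fatty acid desaturase, at -5.04 (SE 0.97). The fat cell marker Plin1 stood at 24.8, 125, 623 and 101 CPM in the 4 young muscles. In the untreated old ones it stood at 7.8, 0.157 and 3.39. Adipocyte markers averaged -3.08 with age in muscle, so a difference in fat tissue was not separated from a change in muscle. Kidney transcripts were present in young 1 and 2, with Kap at 61.5 and 34.2. Of all tested muscle genes 28.8% had no overlap between the groups (chance 5.71%). In total 1372 genes rose and 1333 fell of 16851 tested, 2475 of them without overlap. The count was 811 and 62 without old untreated 2 and 3, and 1265 and 1439 without young 1 and 2. Without old untreated 3 the calls of mt-Co2 (adjusted p = 0.05), Ndufb5 (0.0911), Cox6c (0.0927) and Scd1 (0.0897) were lost while that of Hlf was kept.

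In spleen few single genes passed with age, the B cell regulator Pax5 among them, and the B cell and neutrophil lists lay in opposite directions. Pax5, the B cell lineage regulator (chromosome 4, 44524757 to 44710487), fell from 497 ± 59.9 CPM (SD, n = 4) to 182 ± 14.7 CPM (SD, n = 3), a log2 change of -1.46 (SE 0.16, adjusted p = 0.0234). Gzmk rose by 5.61 (SE 0.71, adjusted p = 0.0388). Pax5 was the only one of 10 B cell markers to fall over all genes, and 7 fell when adjusted over the list alone (camera adjusted p = 1.08e-08, adjusted p = 0.513 with an estimated correlation). None of 12 neutrophil markers passed over all genes, and 11 rose when adjusted over the list alone (camera adjusted p = 4.67e-11, adjusted p = 0.513 with an estimated correlation). Pancreas transcripts stood apart in spleen old untreated 2, with Prss2, a trypsinogen gene, at 235 CPM of the library total and Cela1, an elastase gene, at 264, against at most 2.08 and 23.4 in the other spleens. In spleen young 1 the kidney transcript Kap stood at 37.8, against at most 0.198 in the others. Of all tested spleen genes 35.2% had no overlap between the groups (chance 5.71%). In total 29 genes rose and 24 fell of 19356 tested, all 53 without overlap, and 5460 had an unadjusted p under 0.05. Without old untreated 2, 62 rose and 13 fell. No gene passed without old untreated 1 or without any 1 of young 1 to 4, so every spleen call named here was lost there, with adjusted p for Pax5 of 0.0653, 0.204, 0.23, 0.0924 and 0.114 over a range of 7.04e-16 to 0.23. The count was 1192 without the sex covariate and 3054 by DESeq2.

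In skin, edgeR called 0 of 19188 genes with age (smallest adjusted p = 0.0764, 3064 at an unadjusted p under 0.05), and DESeq2 called 1067. All 22 nuclear oxidative phosphorylation genes were lower, with none passing over all genes or when adjusted over the list alone (camera adjusted p = 6.96e-09, adjusted p = 0.782 with an estimated correlation). Fast skeletal muscle fibre genes averaged -1.11 with age in skin. Among them Ckm stood at 9670, 8010, 11600 and 17200 CPM of the library total in young skin and at 5740, 5980 and 4160 in untreated old skin. A difference in muscle content between the samples was not separated from a change in skin. Of 12 kidney proximal tubule genes none passed over all genes and 9 rose when adjusted over the list alone (camera adjusted p = 6.96e-09, adjusted p = 0.75 with an estimated correlation). The kidney transcript Kap stood at 8.39 and 27.3 CPM in skin old untreated 2 and 3, and old untreated 3 also held albumin at 7080 CPM of the library total. Without old untreated 2 and 3, an alternative chosen after seeing the data that leaves 1 untreated old library, assumed to vary like the other groups, edgeR called 0 genes, with 712 at an unadjusted p under 0.05, and DESeq2 was not run. As edgeR also called 0 genes on all libraries, that fit says nothing on the stability of the count. Krt71, a keratin of the inner root sheath of the hair follicle, stood at 2680 in young 2 and 15200 in old 4F-induced 1 and at no more than 54.5 in the other skin libraries. Without young 2 and old 4F-induced 1, an alternative chosen after seeing the data, 1836 genes passed (889 up, 947 down), and leaving out young 2 alone gave 10 genes.

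**Figure D1:**
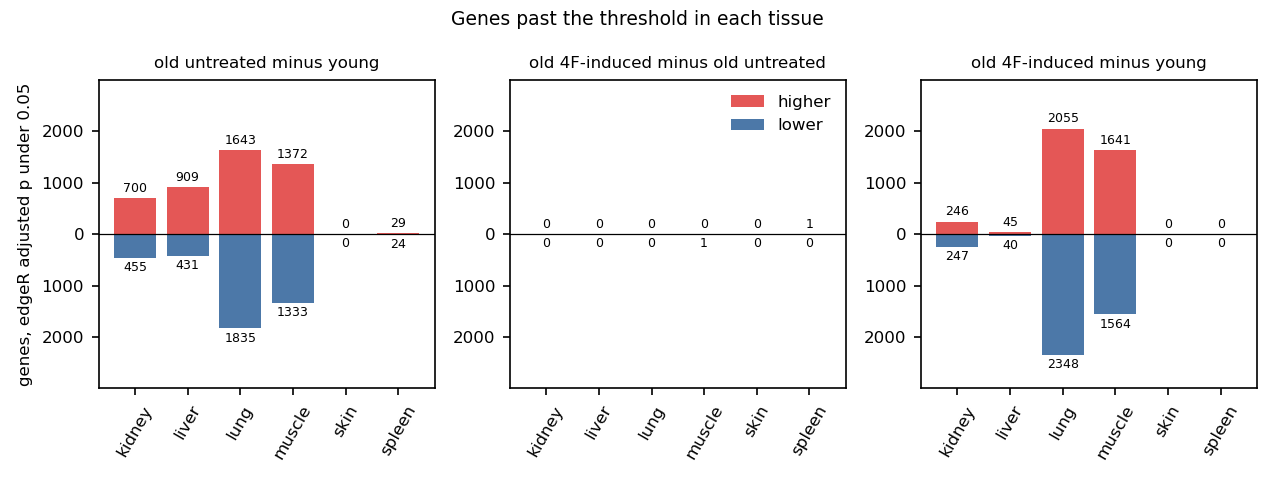
Number of genes called by edgeR (adjusted p under 0.05) per tissue, as bars for higher and lower expression, in each of the 3 comparisons. Counts with age reach 3478 in lung, and induction in old mice gives 1 gene in muscle, 1 in spleen and 0 elsewhere.

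Across tissues, 19 genes rose and 11 fell with age in 4 of 6 tissues and none in 5. Among those, named after their values were seen, Gzmk rose in kidney, liver, lung and spleen by 6.27 on average, the neutrophil calgranulin gene S100a8 by 4.15 and the clock activator Npas2 by 2.63. Per3 changed by -2.02 and Per2 by -1.54, and these 4 did so in kidney, liver, lung and muscle. A permutation test of the variance of list effects between tissues passed for 5 of 47 lists with age, for 2 without muscle old untreated 2 or 3, and for 14, 8 and 3 without skin old untreated 3, young 2 and young 3. It permuted the groups in each tissue separately and so treated the tissues as independent, which libraries from the same animals would not be. Its null is no age effect in any tissue, so a list without a pass may still differ between tissues. Neutrophil markers did not pass, with effects from 1.9 in muscle to 5.32 in liver (permutation adjusted p = 0.619). Nuclear oxidative phosphorylation genes ranged from -0.87 in skin to 0.55 in spleen (permutation adjusted p = 0.0132) and mitochondrially encoded transcripts from -0.60 in liver to 1.40 in muscle (permutation adjusted p = 0.0167). Complement ranged from -0.69 in skin to 1.28 in kidney (permutation adjusted p = 0.025), and proximal tubule and distal nephron lists were highest in skin, at 2.39 and 1.75 (permutation adjusted p = 0.0204 and 0.0276). Kidney transcripts stood apart in single libraries of other tissues, with Kap at 8.39 and 27.3 CPM of the library total in skin old untreated 2 and 3 and at 61.5 and 34.2 in muscle young 1 and 2.

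The second comparison asked what 4F induction changed in old mice. The cassette factors were read first. Pou5f1, a pluripotency factor, was counted 358, 107, 32, 8, 98 and 40 times in old 4F-induced 1 of kidney, liver, lung, muscle, skin and spleen, or 7.06, 3.10, 1.24, 0.255, 4.32 and 2.40 CPM. In old 4F-induced 2 and 3 it was counted 2 and 1, 0 and 0, 1 and 0, 0 and 1, 3 and 1, and 6 and 7 times in the same order, and in untreated old libraries at most 1, 1, 2, 0, 1 and 19 times. A count of 0 in liver allows up to 0.0882 and 0.117 CPM in old 4F-induced 2 and 3 (3 counts of the total, counting error only). Young libraries held at most 0, 0, 0, 4, 3 and 7 Pou5f1 counts in the same order of tissues. Sox2 followed in kidney (270, 0 and 0 counts in the 3 induced libraries), liver (92, 0 and 1) and skin (94, 7 and 10), while lung expressed it in every group. The 4 factors did not pass the test wherever they were tested, Klf4 and Myc in 6 tissues, Sox2 in 3 and Pou5f1 in 1, with adjusted p from 0.352 to 0.988. Without the low-count filter 3 factors were called in kidney.

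**Figure D2:**
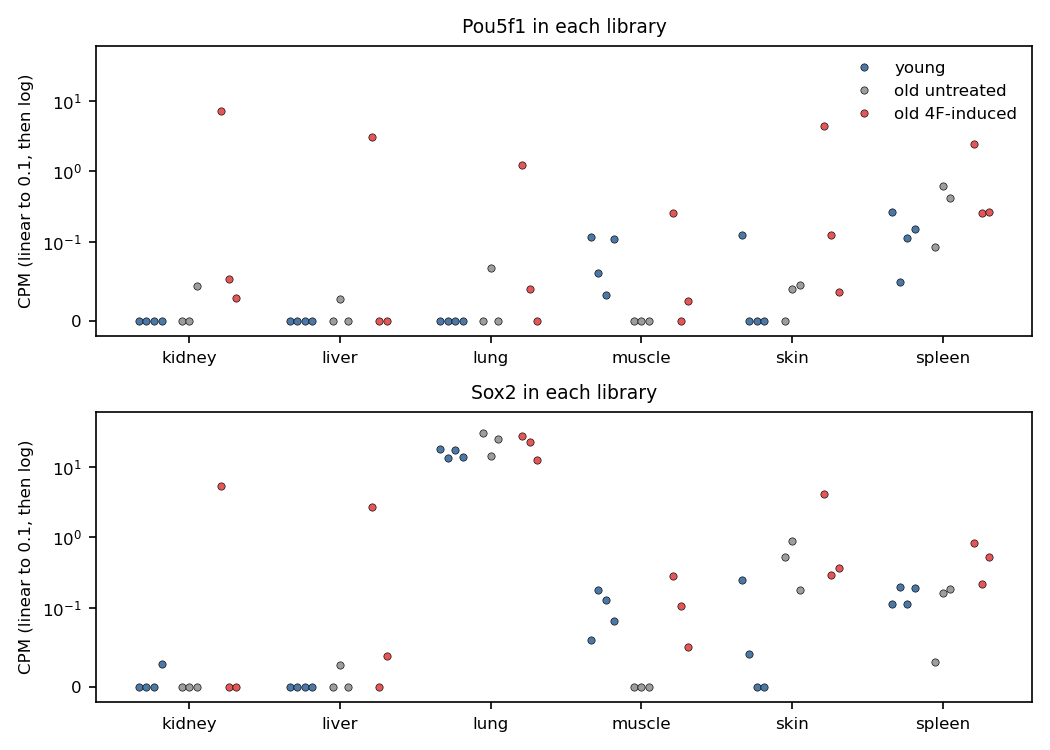
Pou5f1 and Sox2 levels in CPM (symmetric log axis, linear up to 0.1) for each library, by tissue and group. Pou5f1 stands highest in old 4F-induced 1 of each tissue, at 7.06 in kidney and 0.255 in muscle.

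Single genes passed the test of induction in 2 tissues. In muscle, Pdk4, the kinase that restrains pyruvate oxidation (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), fell from 948, 1580 and 980 CPM in untreated old to 133, 131 and 125 CPM in induced old mice, a log2 change of -3.17 (SE 0.27, edgeR adjusted p = 0.0102). In young muscle it stood at 424 ± 105 CPM (SD, n = 4). In spleen, Ebf1, an early B cell regulator (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091), rose from 31.1, 35.2 and 27.8 CPM to 155, 114 and 130 CPM, a log2 change of 2.09 (SE 0.16, adjusted p = 0.00726). In young spleen it stood at 104 ± 12.4 CPM (SD, n = 4). The Pdk4 call was lost without old 4F-induced 1, 2 or 3 (adjusted p = 0.183, 0.0969 and 0.204) and with only both old groups in the fit (0.0667), over a range of 9.94e-30 to 0.204. The Ebf1 call was lost without old 4F-induced 3 (0.0815) or old untreated 1 or 2 (0.101 and 0.0866) and with only both old groups in the fit (0.883), over a range of 1.06e-26 to 0.883.

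In kidney, liver, lung and skin edgeR called 0 genes with induction, with 1068, 3054, 1474 and 1157 at an unadjusted p under 0.05. Muscle had 1071 and spleen 2455 at that level. DESeq2 called 32, 324, 154, 65, 289 and 462 genes in kidney, liver, lung, muscle, skin and spleen. Leaving out 1 library gave 3 genes in kidney without old 4F-induced 1, and 54, 2 and 24 in lung without old 4F-induced 2, old 4F-induced 3 and old untreated 3. In muscle it gave 0 without old 4F-induced 1, 2 or 3 and 2 without old untreated 1. In spleen it gave 55, 2 and 0 without old 4F-induced 1, 2 and 3, and 0, 0 and 6 without old untreated 1, 2 and 3.

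Of 43 to 47 lists tested per tissue with induction, 11 to 22 passed camera at the preset correlation, in both directions. With an estimated correlation, or by fry, 0 passed in each tissue. Cholesterol synthesis genes stood higher in induced than in untreated old mice in all 6 tissues, with median log2 changes of 0.38, 0.66, 0.69, 0.25, 0.58 and 0.34 in kidney, liver, lung, muscle, skin and spleen. None of the 16 to 19 measured members passed over all genes in any tissue, and 10 of 18, 1 of 19, 16 of 19, 0 of 16, 0 of 19 and 3 of 18 rose when adjusted over the list alone. The camera adjusted p was 2.24e-15, 1.27e-08, 2.82e-25, 0.00448, 6.72e-07 and 0.000126, and the adjusted p = 0.297, 0.732, 0.228, 0.881, 0.434 and 0.739 with an estimated correlation. In lung, Sqle, the squalene epoxidase, stood at 0.84 (SE 0.18, adjusted p = 0.428) and Insig1, a sterol sensor of the pathway, at 0.71 (SE 0.16). The camera call was lost in muscle without old untreated 3 (adjusted p = 0.0661, range 0.00026 to 0.0661) and in spleen without old 4F-induced 1 (0.136, range 8.23e-08 to 0.136). The mean log2 change of the list went from 0.47 to 0.22 in spleen without that library, and from 0.39 to 0.25 in kidney without old untreated 2. In skin it went from 0.59 to 0.27, 0.37 and 1.11 without old 4F-induced 1, old untreated 2 and old untreated 3.

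Glucocorticoid-responsive genes stood lower with induction in all 6 tissues, with median log2 changes of -0.43, -1.21, -0.60, -1.21, -0.83 and -0.81. No member passed over all genes, and 4 of 12 in kidney, 1 in lung and 1 in muscle fell when adjusted over the list alone, with 0 in liver, skin and spleen. The camera adjusted p was 7.17e-10, 0.00308, 0.000439, 6.88e-07, 4.5e-05 and 0.00533, and the adjusted p = 0.297, 0.732, 0.611, 0.833, 0.303 and 0.683 with an estimated correlation. Fkbp5, a cochaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), stood at -1.25, -2.08, -1.84, -1.69, -1.70 and -0.90 (SE 0.49, 0.64, 0.68, 0.60, 0.55 and 0.50), and Zbtb16, a zinc finger regulator, at -1.82 in lung (SE 0.40) and -1.53 in muscle (SE 0.28). The camera call was lost in liver without old untreated 1 (adjusted p = 0.0613, range 1.2e-05 to 0.0613) and in spleen without old 4F-induced 1 (0.051, range 0.000152 to 0.051). In muscle the mean log2 change of the list went from -1.01 to -0.49 without old untreated 2. The permutation test of the variance of list effects between tissues passed for 0 of 47 lists with induction (smallest permutation adjusted p = 0.791). Its null is no effect in any tissue, so this does not show equal effects.

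**Figure D3:**
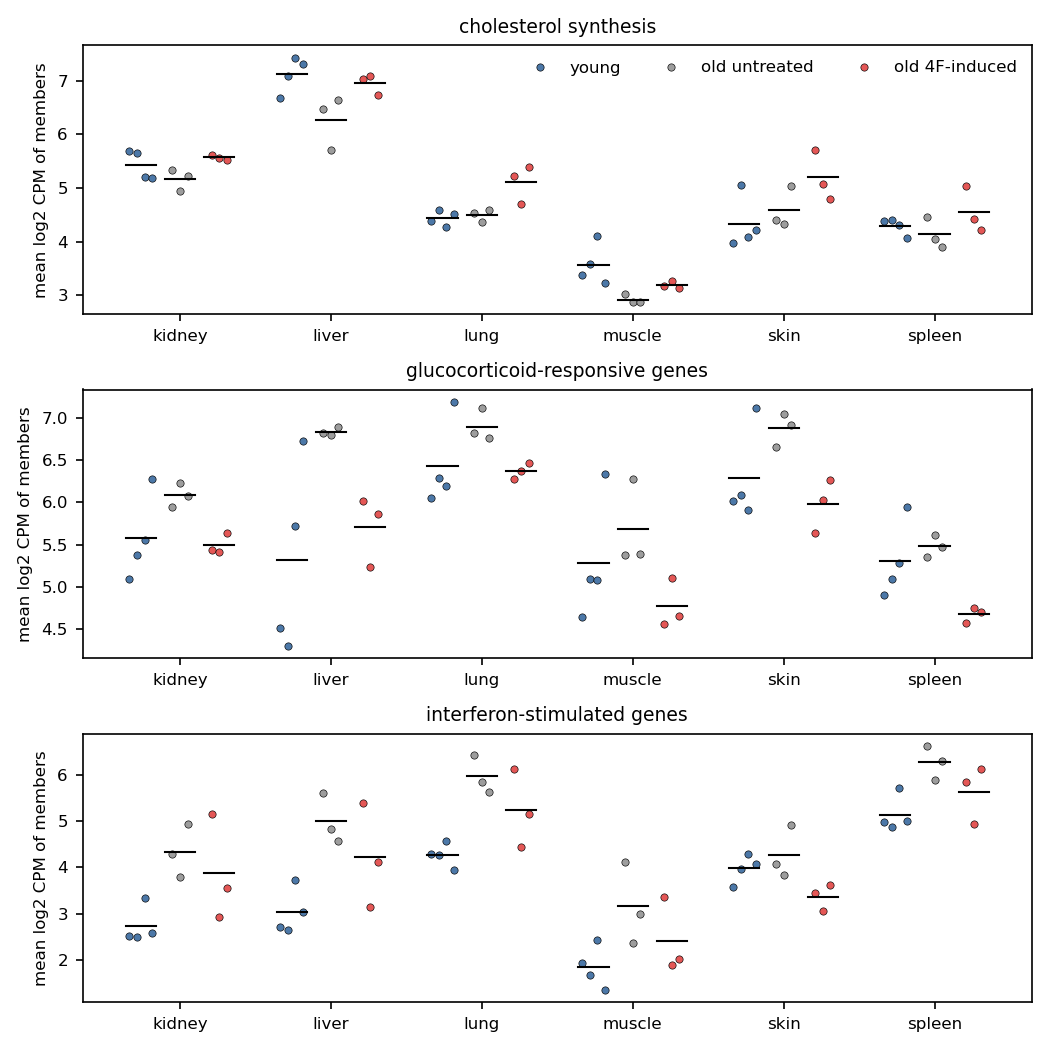
Mean log2 CPM of the cholesterol synthesis, glucocorticoid-responsive and interferon-stimulated lists in each library, by tissue and group, with a black line at each group mean. The glucocorticoid list lies lower in the 3 induced than in the 3 untreated old libraries of each tissue, by 0.52 in lung to 1.13 in liver.

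Interferon-stimulated genes had negative medians with induction in all 6 tissues. In skin 22 of 22 members were negative, of which none passed over all genes and 11 fell when adjusted over the list alone (camera adjusted p = 3.44e-17, adjusted p = 0.25 with an estimated correlation). Gbp2, an interferon-induced GTPase, stood at -1.58 in skin (SE 0.21, adjusted p = 0.629). That list kept its call in skin without any single library and lost it in each other tissue. It was lost in kidney without old 4F-induced 2 or 3 or old untreated 1 or 3 (adjusted p = 0.696, 0.938, 0.133 and 0.729) and in liver without old 4F-induced 2 or 3 or old untreated 1 (0.473, 0.0677 and 0.532). It was also lost in lung without old 4F-induced 2 (0.0849), in muscle without old untreated 1 (0.381) and in spleen without old 4F-induced 2 or old untreated 1 (0.128 and 0.171). Macrophage markers in liver were negative for 12 of 12 members, with none passing over all genes and 9 falling when adjusted over the list alone (camera adjusted p = 9.96e-06, adjusted p = 0.732 with an estimated correlation). In 1 untreated old liver Trem2 stood at 77.9 CPM. In lung these markers were positive for 9 of 12 members (median 0.45), with none passing over all genes or when adjusted over the list alone (camera adjusted p = 0.0022, adjusted p = 0.826 with an estimated correlation). That call was lost without old 4F-induced 1 or 3 or old untreated 1 or 3 (adjusted p = 0.12, 0.794, 0.129 and 0.254). In CPM of the library total Trem2 stood at 61.3, 13.1 and 97.4 in induced against 12.6, 27.2 and 23.7 in untreated old lungs. Macrophage medians were -0.41, -0.17, -0.39 and -0.86 in kidney, muscle, skin and spleen (camera adjusted p = 0.0268, 0.367, 0.17 and 2.08e-07, adjusted p = 0.749, 0.881, 0.707 and 0.683 with an estimated correlation), with none passing over all genes and 5 falling in spleen when adjusted over the list alone. The kidney call was lost without old 4F-induced 3 or old untreated 2 or 3 (0.968, 0.762 and 0.413). Neutrophil markers in spleen were negative for 12 of 12 members, with none passing either way (camera adjusted p = 2.46e-08, adjusted p = 0.683 with an estimated correlation).

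In spleen, B cell markers stood higher with induction for 10 of 10 members, none passing over all genes and 7 rising when adjusted over the list alone (camera adjusted p = 2.65e-13, adjusted p = 0.192 with an estimated correlation). Pancreas transcripts stood apart in the untreated spleen 2, with Prss2 at 235 CPM. Cr2, the complement receptor of mature B cells, stood at 3.28 (SE 0.53, adjusted p = 0.158) and Pax5 at 1.44 (SE 0.16, adjusted p = 0.109). In lung, hepatocyte genes stood lower for 15 of 15 members, with none passing over all genes and 12 falling when adjusted over the list alone (camera adjusted p = 2.82e-25, adjusted p = 0.228 with an estimated correlation). Albumin stood at 263 and 608 CPM of the library total in untreated old lungs 1 and 2. In skin, hair follicle keratins stood higher for 18 of 18 members with none passing (camera adjusted p = 1.6e-09, adjusted p = 0.486 with an estimated correlation), with Krt71 at 15200 CPM in old 4F-induced 1.

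The third comparison set induced old mice against young ones. Of the 12 genes named in each tissue for the largest changes with age, 8 in kidney, 4 in liver, 7 in lung, 10 in muscle and 0 in spleen were called in the same direction here. Both comparisons use the same young libraries, so part of this overlap is built in. With induction 6, 11, 8, 10 and 12 of the 12 had a sign opposite to that with age and none was called, and those comparisons share the untreated old libraries. Trem2 in liver stood at 1.83 (SE 1.30, edgeR adjusted p = 0.523). Examples called in both comparisons were Pik3c2g in kidney at -2.01 (SE 0.08, edgeR adjusted p = 1.02e-05) and Krt23 in liver at -3.28 (SE 0.29, adjusted p = 0.0106). Others were Col6a3 in lung at -1.43 (SE 0.09, adjusted p = 0.00171) and mt-Co2 in muscle at 1.47 (SE 0.19, adjusted p = 0.00696). In spleen Pax5 stood at -0.02 (SE 0.15, adjusted p = 0.952) and Ebf1 at 0.33 (SE 0.14, adjusted p = 0.371). The counts were 246 up and 247 down in kidney, 45 and 40 in liver, 2055 and 2348 in lung and 1641 and 1564 in muscle. In skin and spleen edgeR called 0 genes, with 3030 and 2495 at an unadjusted p under 0.05, and DESeq2 called 818 and 436. Leaving out old 4F-induced 1, 2 and 3 gave 211, 179 and 200 genes in kidney, 1, 74 and 0 in liver, and 1087, 868 and 92 in muscle. Leaving out old 4F-induced 1 and 3 in lung gave 1705 and 1816, old 4F-induced 1 in skin gave 8 and old 4F-induced 2 in spleen gave 258. Leaving out young 1, 2, 3 and 4 gave 146, 86, 288 and 206 in kidney and 7, 0, 19 and 12 in liver. No liver gene passed without old 4F-induced 3 or young 2, so the Krt23 call was lost there. Without young 1, 2 and 4 in lung the counts were 2797, 2655 and 2525, young 1 and 2 in muscle gave 2019 and 1953, and young 2 in skin gave 35.

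Each old library was placed on an axis from the young mean (0) to the old mean (1) of 500 genes chosen with the scored untreated library held out. Held-out untreated old libraries averaged 0.71, 0.82, 0.70, 0.68, 0.61 and 0.75 in kidney, liver, lung, muscle, skin and spleen, and induced old libraries 0.70, 0.53, 0.69, 0.70, 0.57 and 0.60. The differences of -0.01, -0.29, -0.01, 0.02, -0.04 and -0.15 gave exact two-sided permutation p of 1, 0.4, 1, 1, 0.7 and 0.5, where 3 libraries against 3 cannot go below 0.1. Without single libraries the lowest differences were -0.16 in kidney and -0.33 in spleen (without old 4F-induced 1), and -0.52 in liver, -0.38 in lung and -0.28 in skin (without old untreated 3). In lung the exact permutation p was then 0.1, the smallest that 3 against 2 libraries allow. That lung fit kept old untreated 1 and 2, the libraries with liver transcripts, and each was placed on an axis trained on the other. Liver transcripts held by both were not separated from age in that difference. The difference was -0.11 in liver without old untreated 1 and 0.15 in muscle without old untreated 2. The sign of the difference turned in kidney without old 4F-induced 2 or 3 or old untreated 2 (0.05, 0.08 and 0.06) and in lung without old 4F-induced 2 or old untreated 1 or 2 (0.11, 0.04 and 0.06). It turned in skin without old untreated 2 (0.20) and in spleen without old 4F-induced 2 (0.04). In muscle it turned without old 4F-induced 1 or 2 or old untreated 1 or 3 (-0.06, -0.01, -0.02 and -0.11).

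**Figure D4:**
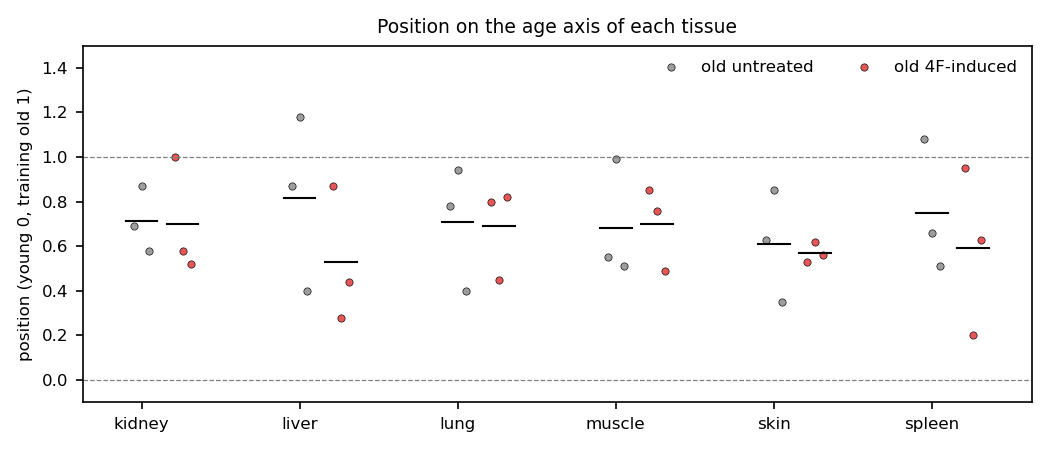
Position of each old library on the age axis of its tissue (0 is the mean of young, 1 the mean of untreated old libraries), with untreated libraries held out in turn and a line at each group mean. Group means differ most in liver, at 0.82 for untreated and 0.53 for induced mice, and the points of both groups overlap.

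Across tested genes, which are not independent replicates, fold changes with induction and with age were negatively correlated, at r of -0.46, -0.76, -0.44, -0.34, -0.79 and -0.64 in kidney, liver, lung, muscle, skin and spleen. Both comparisons use the same untreated old libraries, and 20 simulated sets with no effect of induction gave -0.23, -0.19, -0.20, -0.24, -0.26 and -0.25 on average. The covariance lay below the simulated one by -0.0444, -0.585, -0.185, -0.0423, -1.27 and -0.363. The 3 untreated old libraries were not divided between the comparisons, and the simulation held no variation shared by a whole library. Part or all of the excess may therefore come from those libraries. In skin, where the excess was largest, the held-out axis difference was -0.04. On simulated counts the skin axis recovered only -0.14 of a planted -0.5. A value near 0 there thus cannot tell whether the excess comes from the shared libraries or from induction. This difference of covariances turned positive in muscle without old 4F-induced 3 (0.0203) and in kidney without the sex covariate (0.00328). Without old 4F-induced 1, 2 and 3 it was -0.0939, -0.0217 and -0.0284 in kidney, and without old untreated 1 and 2 -0.0804 and -0.0252. In liver it was -0.377 without old 4F-induced 2, and -0.173 and -1.04 without old untreated 2 and 3. In lung it was -0.047 and -0.0547 without old untreated 1 and 2, the libraries with liver transcripts, -0.333 without old untreated 3, -0.0971 without old 4F-induced 2 and -0.0875 without the sex covariate. In muscle it was -0.0857 without old 4F-induced 1 and -0.117 without old untreated 1, and in skin -0.796 without old 4F-induced 1. In spleen it was -0.665 and -0.0987 without old 4F-induced 1 and 2, and -0.227 and -0.69 without old untreated 1 and 3.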

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

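The tests of tissue differences without single libraries were chosen only after the result was seen, the others were planned, and no explanation was tested for these values. Within the 4 young libraries of a tissue, 1 sample stood apart from the others by Dixon's criterion in 25 of 226 groups, made of 62 named genes, 158 lists and 6 sets of library totals. Chance gives about 1 in 20.

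In kidney, young 3 stood apart for Lyz1 at 0.649 CPM (the others 0.0843 to 0.155), which shares reads with Lyz2, and for Cxcl13, a B cell chemokine, at 0.95 CPM (0.314 to 0.365). Its interferon-stimulated genes averaged 3.33 log2 CPM (2.49 to 2.59). Young 1 stood apart for the chemokine Ccl8 at 0.454 CPM (0.155 to 0.197), and young 2 for immediate early genes at 5.04 log2 CPM (2.85 to 3.21). In liver, clock genes of the BMAL1 phase averaged 2.98 in young 1 (2.82 to 2.83), clock genes of the PER and DBP phase 5.82 in young 4 (5.92 to 5.93) and senescence and secretory genes 0.71 in young 3 (0.04 to 0.15).

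In lung, young 1 stood apart for the heart transcripts Myh6 at 820 CPM (201 to 266), Sbk3 at 58.4 CPM (18 to 23.1) and Kcnj5 at 17.9 CPM (5.26 to 7.02). It also stood apart for slow skeletal muscle fibre genes at 4.91 log2 CPM (3.85 to 4.02) and for mitochondrially encoded transcripts at 6.26 (6.07 to 6.10). Young 2 stood apart for the liver transcripts Ambp and Kng1, each at 0.0385 CPM (0 in the others). That level is below the floor of 3 counts, and any value above 0 would have stood apart there. Young 2 also stood apart for hepatocyte genes at 0.38 log2 CPM (-0.19 to -0.11). In muscle, Ces1f, a carboxylesterase, stood at 41.6 CPM in young 3 (2.79 to 8.32).

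In skin, young 2 stood apart for hair follicle keratins at 8.19 log2 CPM (-2.86 to -2.31), cell cycle genes at 3.65 (1.76 to 1.92) and hepatocyte genes at 3.16 (-0.17 to 0.32). Young 4 stood apart for glucocorticoid-responsive genes at 7.12 (5.91 to 6.09). In spleen, young 2 had a total of 20.2 M counts (25.9 to 26.5 M), young 4 had the decoy receptor gene Il1r2 at 6.25 CPM (2.68 to 3.29). Young 3 had interferon-stimulated genes at 5.73 log2 CPM (4.87 to 5.00) and neutrophil markers at 5.08 (4.07 to 4.17).

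A permutation test of the variance of age effects between tissues treated the tissues as independent, although the labels do not state whether they share animals. Its null is no age effect in any tissue, not equal effects. It passed for 5 lists: nuclear oxidative phosphorylation (adjusted p = 0.0132), mitochondrially encoded transcripts (0.0167), kidney proximal tubule (0.0204), complement (0.025) and kidney distal nephron and podocyte (0.0276). The number of such lists was 2 without muscle old untreated 2 or 3, and 14, 8 and 3 without skin old untreated 3, young 2 and young 3.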

How the results depend on the processing

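The tests without the liver-enriched genes or the libraries with hair keratin, kidney or liver transcripts, and the lists, correlations and tissue differences without single libraries, were chosen only after the result was seen, and the other alternatives here were planned. Of the values of named genes under alternatives other than leaving out a library, 2311 kept their direction and side of the threshold, 478 lost the call, 2 gained it and none reversed, and without single libraries 1565 kept it and 1213 lost it. Of the list values, 1133 kept it, 450 lost the call and 1 reversed, and without single libraries 1285 kept it, 197 lost it and 11 reversed. Where a value changed the cause was not tested, except where fewer libraries or genes were used.

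DESeq2 called these numbers of genes: with age 2188 in kidney, 4467 in liver, 1067 in skin and 3054 in spleen, with 4F induction 32 in kidney, 324 in liver, 154 in lung, 65 in muscle, 289 in skin and 462 in spleen, between induced old and young mice 1478 in kidney, 1036 in liver, 818 in skin and 436 in spleen. Without the low-count filter the counts were: with age 2866 in kidney, 2652 in liver, 3 in skin and 241 in spleen, with 4F induction 251 in kidney, 4 in lung, 56 in muscle and 2 in skin, between induced old and young mice 2287 in kidney, 203 in liver and 2 in spleen. Without the sex covariate they were: with age 101 in kidney, 2538 in liver and 1192 in spleen, with 4F induction 2 in spleen, between induced old and young mice 41 in kidney and 54 in liver. With only the compared groups in the fit they were: with age 351 in liver, 1082 in muscle and 2241 in spleen, with 4F induction 0 in muscle and 0 in spleen, between induced old and young mice 509 in liver. Against a fold change of 1.5 they were: with age 26 in kidney, 31 in liver, 474 in lung, 135 in muscle and 0 in spleen. Without mitochondrial, ribosomal RNA and haemoglobin genes the count was: with age 35 in spleen. Without the 2 skin libraries high in hair keratins it was: with age 1836 in skin, between induced old and young mice 238 in skin. Without the 2 lung libraries with liver transcripts it was: with age 584 in lung, with 4F induction 1 in lung.

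Camera with an estimated correlation passed 0 lists in each tissue with age and with 4F induction. Fry passed 10 in kidney, 1 in liver, 27 in lung, 5 in muscle, 0 in skin and 0 in spleen with age and 0 in each tissue with 4F induction. Without the low-count filter camera passed 19 lists with 4F induction in spleen. The distal nephron and podocyte list in aged kidney turned in camera's direction without the sex covariate (mean log2 change 0.05, camera adjusted p = 0.992). On an axis from all untreated old libraries, which are then also scored, the axis difference was -0.21 in kidney, -0.42 in liver, -0.15 in lung, -0.22 in muscle, -0.35 in skin and -0.34 in spleen. In muscle this reversed the sign, as did leaving out the sex term (-0.08). Without the low-count filter 3 of the cassette factors passed in kidney. Over genes called with age only, which could not be run in skin, the covariance minus the simulated one was -0.424 in kidney, -2.02 in liver, -0.876 in lung, -0.218 in muscle and -2.94 in spleen. Without the sex covariate it was 0.00328 in kidney, -0.498 in liver, -0.0875 in lung, -1.17 in skin and -0.341 in spleen.

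Without single libraries the lowest and highest numbers of genes were as follows. With age they were 127 to 1096 in kidney, 2 to 3782 in liver, 1433 to 2453 in lung, 62 to 3968 in muscle, 0 to 10 in skin and 0 to 75 in spleen. With 4F induction they were 0 to 3 in kidney, 0 to 0 in liver, 0 to 54 in lung, 0 to 2 in muscle, 0 to 0 in skin and 0 to 55 in spleen. Between induced old and young mice they were 86 to 288 in kidney, 0 to 74 in liver, 1705 to 5656 in lung, 92 to 2301 in muscle, 0 to 35 in skin and 0 to 258 in spleen. Lists passing camera with age numbered 23 to 29 in kidney, 22 to 25 in liver, 24 to 29 in lung, 17 to 22 in muscle, 15 to 25 in skin and 13 to 17 in spleen. Those passing with 4F induction numbered 11 to 23 in kidney, 15 to 23 in liver, 14 to 21 in lung, 11 to 19 in muscle, 19 to 25 in skin and 9 to 17 in spleen. The axis difference ranged over -0.16 to 0.08 in kidney, -0.52 to -0.11 in liver, -0.38 to 0.11 in lung, -0.11 to 0.15 in muscle, -0.28 to 0.2 in skin and -0.33 to 0.04 in spleen. The covariance minus the simulated one ranged over -0.0939 to -0.0217 in kidney, -1.04 to -0.173 in liver, -0.333 to -0.047 in lung, -0.117 to 0.0203 in muscle, -1.45 to -0.796 in skin and -0.69 to -0.0987 in spleen. The number of cassette factors called stayed 0 in each tissue. Lists passing the permutation test of the variance between tissues numbered 2 to 14 with age and 0 with 4F induction. List effects whose sign or camera direction turned without a library, as ranges of the mean log2 change, were with age acute phase in skin (-0.63 to 4.84) and cell cycle in skin (-0.38 to 1.99). With 4F induction they were B cell markers in lung (0.05 to 1.82), MHC class I presentation in lung (-0.54 to 0.05), cell cycle in lung (-1.01 to 0.04), cell cycle in skin (-0.54 to 2.04), endothelial markers in muscle (-0.53 to 0.03), interferon-stimulated genes in kidney (-1.24 to 0.35), plasma cell markers in kidney (-0.08 to 0.8) and slow skeletal muscle fibres in skin (-0.51 to 1.49). The distal nephron and podocyte list in aged kidney, which turned in camera's direction without the sex covariate, kept its sign without single libraries (0.13 to 0.19).

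No paired analysis was possible because nothing in the labels pairs libraries between groups: blocks of 6 sample numbers join 1 library of each tissue within a group, and no animal is stated. Library totals limit the detection of Pou5f1 and Sox2, which had 0 to a few counts in many libraries.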

Other observations

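Tests of the 3 patterns below, of the library separation of lists and of the splits for age and 4F induction were chosen only after the result was seen. With 4F induction, erythroid transcripts stood lower in kidney, muscle and skin, with median log2 changes of -1.29, -2.25 and -3.28. None of the 11, 9 and 11 measured members passed over all genes, and 8, 8 and 7 fell when adjusted over the list alone, while 1 rose in muscle. The camera adjusted p was 6.41e-08, 1.03e-10 and 2.76e-09, and the adjusted p = 0.419, 0.751 and 0.399 with an estimated correlation. Hba-a1, an alpha globin gene that shares reads with its copy, stood at -1.27, -2.30 and -3.27 (SE 0.42, 0.65 and 0.79, edgeR adjusted p = 0.856, 0.652 and 0.789). In CPM of the library total it stood at 41.8, 154 and 94.9 in the untreated old kidneys against 48.8, 34.8 and 36.2 in the induced ones, and at 379, 65.5 and 35.5 against 40.1, 18.7 and 18.5 in muscle. In skin it was 17.6, 77.9 and 316 against 10.3, 8.54 and 15.9, and the highest of these, skin old untreated 3, also held kidney transcripts and albumin at 7080 CPM. Fatty acid oxidation genes stood lower in kidney for 15 of 16 members (median -0.38, camera adjusted p = 2.86e-09, adjusted p = 0.422 with an estimated correlation) and in skin for 15 of 16 (median -0.86, camera adjusted p = 1.01e-07, adjusted p = 0.303 with an estimated correlation), with none passing over all genes or when adjusted over the list alone.

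Of 43 lists measured in every tissue, the glucocorticoid-responsive genes were the only one with the 3 induced libraries on the same side of the 3 untreated old libraries in all 6 tissues. Their mean log2 CPM was lower by -0.59, -1.13, -0.52, -0.91, -0.90 and -0.80 in kidney, liver, lung, muscle, skin and spleen (exact two-sided permutation p = 0.1 in each, the smallest that 3 against 3 allows). Chance gives 10% per tissue, and tissues of the same mouse, if blocks of sample numbers mark mice, would not be independent. Cholesterol synthesis genes lay above in kidney, liver, lung and muscle, with exact p of 0.2 in skin and 0.3 in spleen.

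The first pattern weighed was Pou5f1 in 1 induced library of each tissue, with Sox2 in the same library of kidney, liver and skin. In muscle it rests on 8 counts of Pou5f1, against up to 4 in a young muscle library. A swap that put an induced library with Pou5f1 under an untreated label was excluded, since 0 of 18 untreated old libraries came near the Pou5f1 level of old 4F-induced 1 of its tissue, while a swap of libraries without Pou5f1 would not show. Pluripotent cells were excluded as a source, since the summed counts of 5 pluripotency genes were 0.056 of the Pou5f1 count. A single cassette transcript remained open, as the ratio of Sox2 to Pou5f1 differed between kidney (0.759), liver (0.854) and skin (0.9) by a factor of 1.19. The 6 libraries form 1 block of sample numbers and may come from 1 of the 3 induced mice, in which the factors may have been expressed at sampling, and the labels state neither the animal nor the time since doxycycline.

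The second pattern was liver transcripts in 2 untreated old lung libraries. Reads assigned to wrong libraries at an even rate were excluded, since the other 8 lung libraries held at most 0.0639 of the lower liver share. Liver RNA in both libraries stayed open as an explanation, with a Spearman correlation of at least 0.8 with young liver over 174 liver-enriched genes. No biological explanation was tested.

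The third pattern was higher cholesterol synthesis and lower glucocorticoid-responsive genes with induction. A single library as the whole source was excluded for the cholesterol list in kidney, liver and lung (highest adjusted p = 1.18e-08, 2.95e-05 and 3.85e-12) and for the glucocorticoid list in kidney, lung and skin (9.57e-06, 0.0219 and 0.00185), where the camera call at the preset correlation held in each fit without 1 library and the mean log2 change kept at least 0.641 times its size. The limits set left it open for the cholesterol list in muscle (0.25, and 0.18 without old untreated 3, adjusted p = 0.0661), skin (0.59, and 0.27 without old 4F-induced 1, 0.000465) and spleen (0.47, and 0.22 without old 4F-induced 1, 0.136), and for the glucocorticoid list in liver (-1.11, and -0.91 without old untreated 1, 0.0613), muscle (-1.01, and -0.49 without old untreated 2, 0.00652) and spleen (-0.78, and -0.89 without old 4F-induced 1, 0.051). In 3 of these cases only the camera call was lost. The mean log2 change kept at least 0.784 and 0.731 times its size for the glucocorticoid list in liver and spleen. For the cholesterol list in muscle it kept at least 0.72 times its size. These values argue against a single library as the whole source of the change in those 3 cases. The feeding or stress state of the untreated old mice stayed open, since cholesterol synthesis lay below young in untreated old mice and nearer to young in induced ones in 3 of 6 tissues. Another time of collection stayed open too, as the labels give no time. Clock genes of the PER and DBP phase moved 0.213 times as far with induction as with age. Their mean log2 changes with induction were -0.13, 0.54, 0.1, -0.09, -0.24 and 0.43 in kidney, liver, lung, muscle, skin and spleen. With a median standard error of 0.284 the limit set for excluding this explanation could not be reached. An effect of the treatment itself, by the factors or by doxycycline, could also give the pattern. No group received doxycycline without the cassette, so these 2 are not separated. Neither can be told apart from the feeding, stress or time of collection of the mice.

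Other splits of the same libraries were fitted for each count of genes. With age, 1 of 35 splits, the real one, gave as many genes in kidney (1155, highest other 13), liver (1340, highest other 1), lung (3478, highest other 2), muscle (2705, highest other 9) and spleen (53, highest other 1). That is the smallest share that 35 splits allow, and it lies under 0.05 in tissues that may share animals. Without single libraries the counts fell to as low as 2 in liver and 0 in spleen. In skin all 35 gave as many as the real 0 (edgeR; 3064 at an unadjusted p under 0.05, 1067 by DESeq2; highest other 19), so chance was not excluded. For induced old against young mice, 1 of 35 splits gave as many in kidney (493, highest other 3), lung (4403, highest other 0) and muscle (3205, highest other 1), a share under 0.05. Chance was not excluded in liver (2 of 35 splits, real 85, highest other 160), skin (35 of 35, real 0, 3030 at an unadjusted p under 0.05, 818 by DESeq2, highest other 28) or spleen (35 of 35, real 0, 2495 at an unadjusted p under 0.05, 436 by DESeq2, highest other 597). The 597 genes of 1 other spleen split point to a structure among the samples, whose source was not tested. For 4F induction, 10 splits are too few for a share under 0.05: the real and highest other counts were 0 and 1 in kidney, 0 and 4 in liver, 0 and 3 in lung, 1 and 5 in muscle, 0 and 0 in skin, and 1 and 12 in spleen, with 10, 10, 10, 2, 10 and 4 splits giving as many.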
